A study of Homo sapiens with 12 samples.

How the data were processed

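The series measured gene expression in CD207-positive cells sorted from lesions of Langerhans cell histiocytosis (LCH), a disease in which CD207-positive dendritic cells with an activated mitogen-activated protein kinase (MAPK) pathway collect in tissue. It holds 12 arrays in 3 groups of 4, named here DMSO (the solvent control), BRAFi (vemurafenib, an inhibitor of the kinase BRAF) and MEKi (trametinib, an inhibitor of the kinase MEK). Per the labels' protocols, thawed lesion cells were treated with DNase and kept overnight in medium without serum, and the inhibitors were given for 12 hours before the sort. Per the labels, the dose of vemurafenib was 100 µM and that of trametinib 10 mM. The trametinib figure is given here as the labels state it, and whether it is a dose or a stock was not settled. RNA was isolated with the PicoPure kit, amplified with the WT-Ovation Pico system and labelled with biotin by the FL-Ovation module, per the labels' protocols.

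The deposited values are on a log2 scale. They are RMA summaries, 1 per probe set and array, made in Affymetrix Expression Console, per the submitters' processing notes. The versions, the array library files and the genome build are not given in the sources used here. The base of the logarithm is not written in the table. It was taken as log2 because the values span the range that RMA gives on that scale, so folds printed here rest on that reading. RMA subtracts a modelled background, gives the probes of the arrays run together a common distribution and summarises them with a robust fit, and changes of dim probe sets come out smaller than they are. Whether all 12 arrays were run through RMA together is not given in the sources used here.

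The table holds 70523 probe sets of the Affymetrix Human Transcriptome Array 2.0, the array named by the platform annotation. Of these, 1529 are control probe sets. In the platform annotation 23784 probe sets pair with 1 gene symbol, 1540 with several and 45199 with none. Symbols were brought up to date through the gene ID for 21497 of the single-symbol probe sets, as a current symbol for 1977 and through a synonym for 306, and 4 kept the platform's symbol. Probe sets without a single symbol were not named and entered only the counts over probe sets. The 88 single-symbol probe sets of XIST, TSIX and genes on the Y chromosome were left out of every step, and pseudoautosomal genes, which lie on both sex chromosomes, were kept. A gene was represented by its probe set with the highest mean over all 12 arrays. That gave 22349 genes, of which 505 had more than 1 probe set and 17138 were protein coding. The 2 probe sets of ENO1 differed in direction with MEKi, at -1.11 and 0.92 on the log2 scale. Signals named MIR221 and MIR222 come from probe sets of the precursor genes and measure no arm of the mature microRNA.

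Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). One model held all 3 groups, with the number of the paired sample as a fixed block, and had 6 residual and 8.24 moderated degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all 22349 genes, and a gene passed at an adjusted p under 0.05. The contrasts were BRAFi against DMSO, MEKi against DMSO, the mean of both inhibitors against DMSO, and MEKi against BRAFi. Errors of log2 changes are the model's standard errors. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

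The titles call arrays with the same number a biological paired sample, which is the source of the pairing. It was checked on the deviations of the arrays from their group means: array pairs of the same number correlated at 0.298 to 0.785, those of different number and group at -0.462 to 0.192, and 12 of 12 arrays correlated best with their own number. No 2 arrays had identical values (0 pairs). The labels do not say that each number is a different person, so p-values speak for these samples. With the block in the model they rest on the spread left within the paired samples, and not on the spread between samples.

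Gene lists were fixed before the data were examined, as were the design, the rule for named genes and all alternatives but 3. There were 33 lists, 21 of cell programmes and 12 of marker genes of other cell types that a lesion or a sort could hold. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 33 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry asks whether a list's genes move, on balance, 1 way. For each list the members past the threshold were counted over all genes tested and also adjusted over the list alone. Of the 24 genes with the largest changes named for each inhibitor and for their mean, 12 rose and 12 fell, and all had an adjusted p under 0.05 and the same sign in 4 of 4 pairs. For MEKi against BRAFi the numbers were 6 and 6. In addition the study genes, the drug target kinases and up to 4 members of every other list, those with the smallest p, could be named. The study genes were chosen from the series title (CCR7, its ligands, and BCL2-family genes).

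Both inhibitors were compared with the same DMSO arrays. The similarity of the responses was therefore set beside 100 simulations of unchanged groups against shared controls and beside the 6 ways to give each inhibitor its own 2 pairs. Control probe sets, RNA classes and the range of values were compared between groups with an exact permutation test of 4 against 4 arrays, which has 70 arrangements and a smallest two-sided p of 0.0286. This test leaves the pairing aside. An exact test that exchanges arrays only within the 4 pairs was therefore run beside it, with 16 arrangements and a smallest two-sided p of 0.125, so it cannot pass the threshold.

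Alternatives, each changing 1 choice, were: no pair block, leaving out each pair in turn, the mean of all probe sets of a gene, leaving out the dimmer part of the genes (those under the median level), eBayes with trend and robust settings, array quality weights, quantile normalization once more, centring each array on its median, only the 2 compared groups in the fit, and every probe set tested on its own. Cyclic loess (span 0.7), a test of protein-coding genes only and the exchanges of array measures within pairs were added after seeing the data.

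The tests were tried on simulated data with 200 changed genes among 22349, 50 at each fold. At a 2-fold change 72% of the changed genes were called for BRAFi against DMSO, 80% for MEKi against DMSO, 70% for the mean and 74% for MEKi against BRAFi. At 4-fold the shares were 98%, 98%, 100% and 98%, and at 1.41-fold 40%, 48%, 40% and 44%. Unchanged genes made up 5.62%, 4.37%, 4.09% and 4.47% of the calls. Of 200 unchanged lists, 0.5%, 2%, 4% and 3.5% had a p under the threshold. The simulated noise was drawn for each gene on its own, with the same spread on every array, and few genes were changed. These shares therefore do not cover lists whose genes vary together, such as the interferon list, with an estimated correlation of 0.543. Nor do they cover arrays of unequal spread or a shift common to many genes. With 50 genes at each fold, differences in these shares between the contrasts were not tested.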

Results

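Gene expression was measured on 12 arrays of CD207-positive cells sorted from LCH lesions. CD207 (langerin) is a lectin of Langerhans cells, the dendritic cells of the epidermis, and LCH lesion cells carry it. The arrays formed 3 groups of 4 paired samples: DMSO, BRAFi (vemurafenib) and MEKi (trametinib), each given for 12 hours. The labels give 100 µM for vemurafenib and 10 mM for trametinib. The series asks how inhibitor treatment changes gene regulation in lesion cells, and its title concerns MAPK activation, migration through CCR7 and survival. The number of arrays limits the precision. Changes are given as differences of RMA values on the log2 scale with the model's standard errors. These errors come from the fit of all 12 arrays and do not give the spread between the 4 pairs of a comparison.

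The MEKi arrays stood apart from the other 8 in measures that involve no single gene. Background control probe sets had a mean of 3.67 ± 0.117 (SD, n = 4) with MEKi and 3.27 ± 0.0519 (SD, n = 4) with DMSO. Hybridization controls had means of 12.6 ± 0.348 and 11.7 ± 0.323. The 92 ERCC probe sets, a further set of controls, had means of 5.05 ± 0.0534 and 4.85 ± 0.0604. Each difference had an exact permutation p of 0.0286 (two-sided), the smallest that 70 arrangements allow, and 0.0546 after adjustment over 42 tests. The highest value on an array was 19.2 ± 0.0742 with MEKi and 19.9 ± 0.0344 with DMSO. The 1343 control probe sets named by a number had a median of 7.33 ± 0.126 with MEKi and 7.73 ± 0.254 with DMSO, against the direction of the background and hybridization controls (difference -0.403, exact permutation p = 0.0571, adjusted p = 0.0959). BRAFi arrays differed from DMSO by 0.0178 in background (exact permutation p = 0.771), within the spread between arrays. Labelling spike-ins, probe sets for RNA that can be added before labelling, stood at 5.35 ± 0.167 with BRAFi and 4.94 ± 0.198 with DMSO, a difference of 0.41 (exact permutation p = 0.0286, adjusted p = 0.0546). These 4 probe sets lay under the median of all probe sets (5.60 and 5.61), so the difference is between low signals. The 24 genes of small nuclear RNAs, parts of the splicing machinery, had a median of 11.6 ± 1.28 with MEKi and 9.53 ± 1.12 with DMSO (exact permutation p = 0.0286, adjusted p = 0.0546). These permutations leave the pairing aside. Exact exchanges within the 4 pairs have 16 arrangements and cannot give a two-sided p below 0.125, the value they gave for each of these differences except the BRAFi background (0.625).

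**Figure D1:**
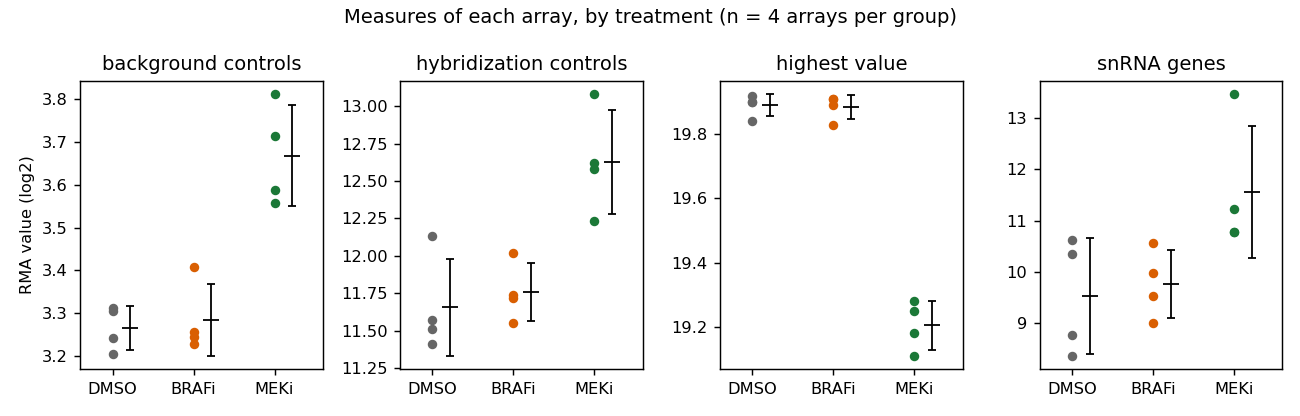
Measures of each array by treatment, as RMA values on the log2 scale (points, 4 arrays per group; bars, mean ± SD). The 4 MEKi arrays had background controls of at least 3.56, against at most 3.41 on the other 8 arrays, and a lower highest value, while the snRNA genes were higher with MEKi under every scaling tried.

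BRAFi against DMSO asked which genes changed with vemurafenib. Inhibition of the kinase itself was not measured here. CCR7, the chemokine receptor that leads dendritic cells to lymph nodes, had the largest rise, 16.4-fold (log2 change 4.04 ± 0.54, the model's SE, adjusted p = 0.0124, higher in 4 of 4 pairs). CRLF2, a chain of the receptor for the cytokine TSLP, rose 15.2-fold (3.92 ± 0.27, adjusted p = 0.00142), and IDO1, which breaks down tryptophan, 10.6-fold (3.40 ± 0.35, adjusted p = 0.00468). The microRNA precursor gene MIR221 fell the furthest, 38.9-fold (-5.28 ± 0.27, adjusted p = 0.000436). PLAUR, the urokinase receptor, fell 13.5-fold (-3.75 ± 0.29, adjusted p = 0.00242). Each of these moved the same way in 4 of 4 pairs. In all, 373 of 22349 genes passed, 207 higher and 166 lower, and 215 of them changed 2-fold or more.

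The other 9 largest rises were of ARAP2 (2.97 ± 0.16), P2RY10 (2.81 ± 0.40), DAPP1 (2.76 ± 0.32), LAMP3 (2.75 ± 0.44), NR4A3 (2.65 ± 0.41), SLC9A9 (2.61 ± 0.27), HLA-DOB (2.59 ± 0.18), ADAMDEC1 (2.47 ± 0.21) and CALCRL (2.47 ± 0.33). LAMP3 is a lysosomal protein of mature dendritic cells, and HLA-DOB is a chain of the MHC class II modulator HLA-DO. After MIR221 and PLAUR, the largest falls were of CLEC5A (-2.93 ± 0.47), a myeloid activating lectin, SLAMF8 (-2.92 ± 0.27), SPRY2 (-2.82 ± 0.25), a feedback inhibitor of receptor signalling to ERK, CDCP1 (-2.79 ± 0.27), EMP1 (-2.77 ± 0.38), RESF1 (-2.63 ± 0.30), MTSS1 (-2.63 ± 0.35), ARHGAP18 (-2.50 ± 0.29), NRP1 (-2.45 ± 0.33) and ANKH (-2.20 ± 0.22). Their adjusted p-values lay between 0.000448 for ARAP2 and 0.0252 for CLEC5A, and each moved the same way in 4 of 4 pairs.

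Of the 8 study genes, CCR7 and BCL2L11 rose with BRAFi and 6 did not pass (3 rose and 0 fell adjusted over the list alone). The list was drawn from the series title, so it is not independent evidence of its direction. BCL2L11, which encodes the pro-apoptotic protein BIM, rose 2.32-fold (1.22 ± 0.16, adjusted p = 0.0113, 4 of 4 pairs). The survival genes BCL2A1 (1.08 ± 0.35, adjusted p = 0.234, higher in 4 of 4 pairs), BCL2 (0.71 ± 0.34, 0.491, 4 of 4), MCL1 (-0.34 ± 0.26, 0.769, lower in 3 of 4) and BCL2L1 (0.15 ± 0.20, 0.888, higher in 3 of 4) did not pass, nor did the CCR7 ligands CCL19 (-0.10 ± 0.10, 0.847) and CCL21 (0.02 ± 0.09, 0.98). The list's median change was 0.43 (camera adjusted p = 0.00345, and adjusted p = 0.169 with an estimated correlation).

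Genes of ERK output and feedback were lower with BRAFi. Of 20 members 6 fell and 0 rose (10 fell and 1 rose adjusted over the list alone), with a median of -0.27 (camera adjusted p = 1.78e-07, and adjusted p = 0.169 with an estimated correlation). Besides PLAUR and SPRY2 these included CCND1, which encodes cyclin D1 (-1.33 ± 0.17, adjusted p = 0.00977), and SPRY4 (-0.85 ± 0.13, adjusted p = 0.0208). SPRED1 and DUSP6 (-1.74 ± 0.32, adjusted p = 0.0422), named after their values were seen, also fell. Of 18 immediate early genes only NR4A3, a nuclear receptor, rose and 0 fell (2 rose and 0 fell adjusted over the list alone, median 0.21, camera adjusted p = 0.0245, and adjusted p = 0.757 with an estimated correlation). ATF3 (0.99 ± 0.23, adjusted p = 0.0871) and EGR1 (-0.99 ± 0.32, adjusted p = 0.24) lay on either side of 0. The 4 measured kinases of the targeted pathway did not pass: ARAF (0.22 ± 0.12, adjusted p = 0.565), MAP2K1 (-0.36 ± 0.18, 0.523), MAP2K2 (-0.02, 0.98) and MAPK3 (-0.02, 0.981), with a camera adjusted p of 0.971.

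Genes of dendritic cell maturation rose with BRAFi: 10 of 23 members passed, all higher (15 rose and 1 fell adjusted over the list alone), among them CCR7, LAMP3, IDO1, CXCR4 (2.43 ± 0.30, adjusted p = 0.00868) and CD83 (2.12 ± 0.30, adjusted p = 0.0149). The median was 0.61 (camera adjusted p = 2.06e-16), and this list alone also passed with an estimated correlation (adjusted p = 0.0027). Of 13 genes of antigen presentation on MHC class II, 4 rose and 0 fell (11 rose and 1 fell adjusted over the list alone): the protease gene CTSS (1.08 ± 0.18, adjusted p = 0.0278), HLA-DPB1 (0.91 ± 0.16, 0.0332), HLA-DOA (1.05 ± 0.18, 0.0344) and HLA-DQB1 (1.18 ± 0.21, 0.0369). Their median was 0.74 (camera adjusted p = 2.59e-12, and adjusted p = 0.118 with an estimated correlation). None of the 21 interferon-stimulated genes passed over all genes, while 18 rose and 0 fell adjusted over the list alone, with a median of 1.74 (camera adjusted p = 6.83e-19, and adjusted p = 0.169 with an estimated correlation). IFI44L stood at 2.26 ± 0.44 (adjusted p = 0.0511) and HERC5 at 2.45 ± 0.51 (adjusted p = 0.0605), each higher in 4 of 4 pairs. Of 16 NF-kB targets 4 rose and TNF fell (8 rose and 3 fell adjusted over the list alone, median 0.34, camera adjusted p = 0.000634, and adjusted p = 0.377 with an estimated correlation). REL, an NF-kB subunit, stood at 1.37 ± 0.17 (adjusted p = 0.00977) and TNFAIP2 at 1.41 ± 0.22 (adjusted p = 0.0211).

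Among 22 genes of the senescence-associated secretory phenotype, secreted inflammatory and matrix factors, TNF fell (-2.01 ± 0.34, adjusted p = 0.0314) and 0 rose (8 fell adjusted over the list alone, median -0.33, camera adjusted p = 0.0033, and adjusted p = 0.379 with an estimated correlation). Of 14 cholesterol synthesis genes SQLE, the squalene epoxidase, fell (-1.82 ± 0.26, adjusted p = 0.0163) and 0 rose. The list's median was 0.30 and it was called higher (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00676, and adjusted p = 0.379 with an estimated correlation). Of 17 ATF4 and endoplasmic reticulum stress genes 0 passed (2 fell adjusted over the list alone, median -0.12, camera adjusted p = 0.0124, and adjusted p = 0.379 with an estimated correlation). Of 13 T cell markers 1 rose, IL7R, a cytokine receptor that dendritic cells can also make (1.58 ± 0.30, adjusted p = 0.0457). The list was called higher (1 rose adjusted over the list alone, median 0.06, camera adjusted p = 0.0466, and adjusted p = 0.5 with an estimated correlation). Of 7 osteoclast markers 1 fell, DCSTAMP, a fusion protein also made by dendritic cells (-1.18 ± 0.19, adjusted p = 0.0266). The list was called lower (3 fell adjusted over the list alone, median -0.10, camera adjusted p = 0.0162, and adjusted p = 0.379 with an estimated correlation).

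Camera did not call the remaining lists with BRAFi, and neither did fry. Of 22 chemokines and their receptors 0 passed (1 rose adjusted over the list alone, camera adjusted p = 0.14), with CXCL16 at 1.30 ± 0.27 (adjusted p = 0.0611). Of 8 anti-apoptotic genes 0 passed (1 rose adjusted over the list alone, camera adjusted p = 0.14), with BIRC2 at 0.62 ± 0.13 (adjusted p = 0.0664). Of 14 pro-apoptotic genes BCL2L11 and the death receptor gene FAS (0.84 ± 0.09, adjusted p = 0.00463) rose and 0 fell (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.672). Of 16 Langerhans cell and LCH markers 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.821), and CD207 stood at -0.95 ± 0.48 (adjusted p = 0.536, lower in 3 of 4 pairs). PFKFB3 (-0.85 ± 0.12, adjusted p = 0.017) and the glucose transporter gene SLC2A3 (-1.82 ± 0.26, adjusted p = 0.017) fell among 20 genes of glycolysis and hypoxia (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.707). LRRC25 fell (-0.44 ± 0.08, adjusted p = 0.0439) among 7 aryl hydrocarbon receptor targets (1 adjusted over the list alone, camera adjusted p = 0.834). None passed of 24 cell cycle (0.539), 8 heat shock (0.707), 18 lysosome and autophagy (0.43) and 12 ribosome biogenesis genes (0.626).

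Among markers of other cell types PECAM1, an adhesion molecule that leukocytes also carry, fell with BRAFi (-1.17 ± 0.21, adjusted p = 0.0355, 1 of 7 endothelial markers, camera adjusted p = 0.482). Camera adjusted p-values were 0.674 for B and plasma cells, 0.672 for NK cells, 0.707 for macrophages and monocytes, 0.647 for eosinophils and 0.707 for neutrophils. They were 0.674 for plasmacytoid dendritic cells, 0.148 for fibroblasts, 0.821 for keratinocytes and 0.147 for erythroid cells. The median, mean and test differed in sign for the kinases, pro-apoptotic genes, glycolysis, aryl hydrocarbon receptor targets and keratinocyte markers.

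Without the pair block 54 genes passed for BRAFi in place of 373, without 1 pair 62 to 177, and 4 of the 24 genes with the largest changes (MIR221, PLAUR, SLAMF8 and ADAMDEC1) passed under every alternative. The adjusted p of CCR7 was 0.117 without the block (range over its alternatives 0.00104 to 0.117), that of CRLF2 0.0947 (0.000342 to 0.0947), that of LAMP3 0.0735 (0.00843 to 0.144) and that of BCL2L11 0.803 (0.00376 to 0.803).

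**Figure D2:**
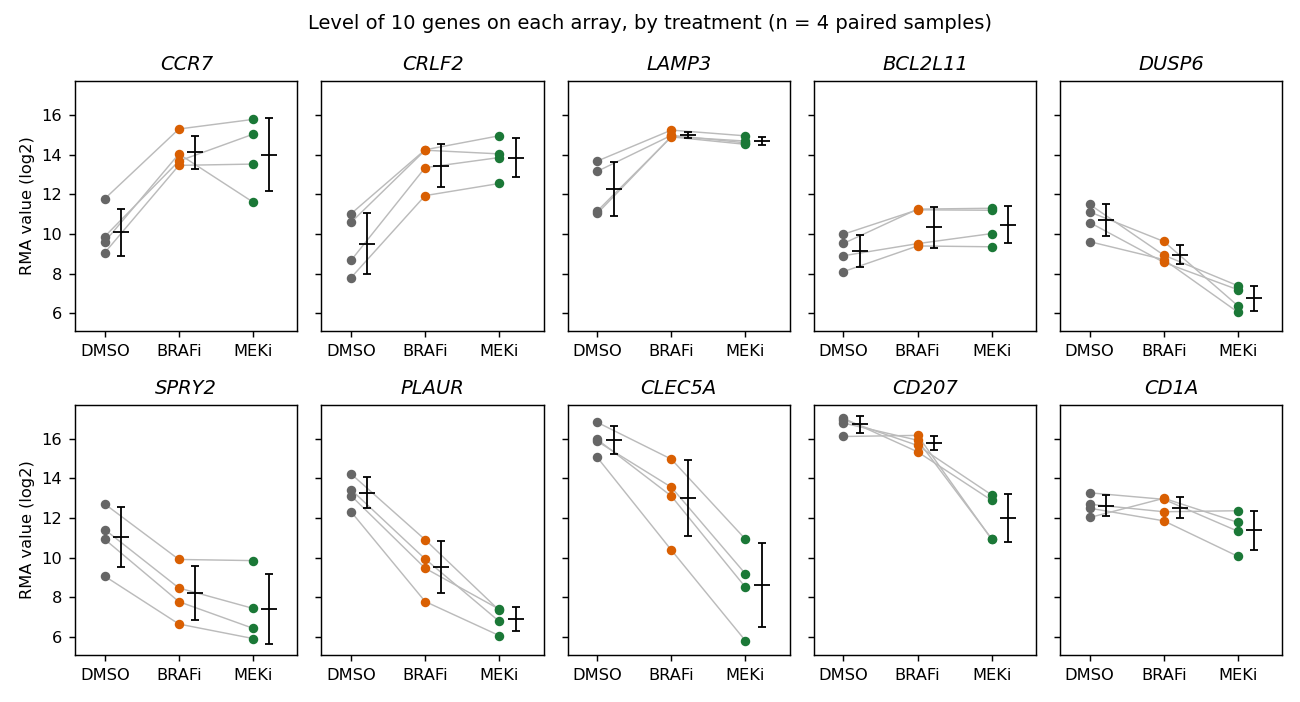
RMA value (log2) of 10 genes on each array by treatment (points, grey lines joining the 4 paired samples; bars, mean ± SD). CCR7 had a mean of 10.1 with DMSO, 14.1 with BRAFi and 14.0 with MEKi, and CD207 16.7, 15.8 and 12.0; CD1A was added after its values were seen.

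MEKi against DMSO asked the same of trametinib. CLEC5A fell the furthest, 160-fold (-7.32 ± 0.47, adjusted p = 0.000118), followed by PLAUR, 83.2-fold (-6.38 ± 0.29, adjusted p = 6.66e-05), the macrophage elastase gene MMP12, 61-fold (-5.93 ± 0.68, adjusted p = 0.000814), and MIR221, 57.3-fold (-5.84 ± 0.27, adjusted p = 6.66e-05). CD207 fell 26.7-fold (-4.74 ± 0.48, adjusted p = 0.000482). CRLF2 rose 20.2-fold (4.33 ± 0.27, adjusted p = 0.000113) and CCR7 15-fold (3.91 ± 0.54, adjusted p = 0.00164). Each moved the same way in 4 of 4 pairs. In all, 7644 of 22349 genes passed, 4274 higher and 3370 lower, and 1549 changed 2-fold or more, 407 higher and 1142 lower. The direction of the calls went with the level of the gene: of genes under the median level 2912 rose and 98 fell, of those at or above it 1362 rose and 3272 fell, on arrays whose background controls were 0.402 higher than with DMSO.

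Further large rises with MEKi were of ZFP36 (3.66 ± 0.37), which encodes an RNA-binding protein that destabilises cytokine messages, SCARNA7 (3.35 ± 0.48), RASD1 (3.31 ± 0.50), SNORD60 (3.18 ± 0.86), RNU5D-2P (3.11 ± 0.51), RNU5E-2P (3.10 ± 0.51), RNU5A-1 (2.99 ± 0.41), RNU5B-1 (2.90 ± 0.33), MTRNR2L2 (2.85 ± 0.33) and VTRNA1-1 (2.80 ± 0.53). Small nuclear RNAs rose in 9 of 24 genes and fell in 0, with a median of 1.23, and did so in 6 to 9 genes under 3 other scalings. Further large falls were of CCL1 (-5.53 ± 0.59), IL1B (-5.40 ± 0.71), the gene of the cytokine interleukin 1 beta, CCL2 (-4.67 ± 1.07), TNFSF10 (-4.65 ± 0.81), SLAMF8 (-4.61 ± 0.27), SQLE (-4.25 ± 0.26) and NRP1 (-4.12 ± 0.33). Adjusted p-values of these 17 genes lay between 9.47e-05 for SLAMF8 and 0.0245 for SNORD60, each with the same sign in 4 of 4 pairs.

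Of the 8 study genes 4 rose and MCL1 fell with MEKi (4 rose and 2 fell adjusted over the list alone), and the list, drawn from the title and so no independent evidence of its direction, was not called by camera (median 0.19, camera adjusted p = 0.51). Fry, which does not compare a list with other genes, called it higher (adjusted p = 0.0271, 0.0271 to 0.744 over its alternatives). BCL2L11 rose 2.53-fold (1.34 ± 0.16, adjusted p = 0.0009, 4 of 4 pairs) and BCL2 2.26-fold (1.18 ± 0.34, adjusted p = 0.03, 4 of 4 pairs). MCL1 fell by 1.05 ± 0.26 (adjusted p = 0.0191, 4 of 4 pairs). CCL21 rose by 0.27 ± 0.09 (adjusted p = 0.0407), on arrays whose median over all probe sets was 0.189 higher with MEKi than with DMSO. BCL2A1 (-1.02 ± 0.35, adjusted p = 0.0539, lower in 3 of 4 pairs), CCL19 (0.12, 0.396) and BCL2L1 (-0.05, 0.863) did not pass. Of the kinases MAP2K1, which encodes MEK1, fell (-1.13 ± 0.18, adjusted p = 0.00302, 4 of 4 pairs). ARAF (-0.23 ± 0.12, adjusted p = 0.154), MAP2K2 (0.11, 0.458) and MAPK3 (0.12, 0.292) did not pass (1 of 4 fell adjusted over the list alone, median -0.06, camera adjusted p = 0.451).

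Genes of ERK output and feedback fell in 11 of 20 members and rose in 4 (11 and 4 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.00229, and adjusted p = 0.586 with an estimated correlation). DUSP6, a phosphatase that switches off ERK, fell 15.4-fold (-3.95 ± 0.32, adjusted p = 0.000209), SPRY2 by 3.62 ± 0.25 (adjusted p = 0.000129) and CCND1 by 1.71 ± 0.17 (adjusted p = 0.0004). The members that rose, named after their values were seen, were IER3 (2.75 ± 0.55), SPRY1 (0.29 ± 0.08), EPHA4 (0.26 ± 0.06) and LIF (0.21 ± 0.06), and 1 member of the list rose after quantile normalization once more. Of 18 immediate early genes 11 rose and MYC, named after its values were seen, fell (13 rose and 1 fell adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.0114, and adjusted p = 0.699 with an estimated correlation). Examples were ZFP36, JUNB (2.13 ± 0.35, adjusted p = 0.00376), NR4A3 (2.35 ± 0.41, adjusted p = 0.0045) and ATF3 (1.51 ± 0.23, adjusted p = 0.00253).

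Senescence-associated secretory genes fell in 12 of 22 members and rose in 1 (12 and 1 adjusted over the list alone, median -0.79, camera adjusted p = 0.000824, and adjusted p = 0.586 with an estimated correlation). Besides MMP12 and IL1B these included TIMP1, an inhibitor of matrix proteases (-1.08 ± 0.11, adjusted p = 0.000558), and MMP14 (-3.08 ± 0.61, adjusted p = 0.00782). Langerhans cell and LCH markers fell in 7 of 16 members and rose in 1 (8 fell and 1 rose adjusted over the list alone, median -0.34, camera adjusted p = 0.0317, and adjusted p = 0.586 with an estimated correlation). CD207, CD52 (-1.09 ± 0.25, adjusted p = 0.0141) and the lipid-presenting CD1E (-1.39 ± 0.36, adjusted p = 0.0221) fell, and the transcription regulator ID2 rose (1.19 ± 0.24, adjusted p = 0.00873). CD1A, named after its values were seen, fell by 1.24 ± 0.39 (adjusted p = 0.0407, 4 of 4 pairs). Of 24 cell cycle genes 4 fell and 0 rose (4 adjusted over the list alone, median -0.21, camera adjusted p = 0.0251, and adjusted p = 0.596 with an estimated correlation), among them MKI67 (-1.18 ± 0.25, adjusted p = 0.00963) and AURKA (-0.51 ± 0.07, adjusted p = 0.00201).

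Of 12 ribosome biogenesis genes 11 fell and 0 rose (11 adjusted over the list alone, median -0.88, camera adjusted p = 3.51e-07, and adjusted p = 0.586 with an estimated correlation). Examples were RRS1 (-2.78 ± 0.30, adjusted p = 0.000652), NOP16 (-2.17 ± 0.19, adjusted p = 0.000284) and NOLC1 (-1.83 ± 0.17, adjusted p = 0.000335). Of 14 cholesterol synthesis genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.999, camera adjusted p = 3.26e-05, and adjusted p = 0.586 with an estimated correlation). Examples were SQLE, MSMO1 (-2.80 ± 0.18, adjusted p = 0.000118) and CYP51A1 (-2.21 ± 0.30, adjusted p = 0.00156). Of 20 genes of glycolysis and hypoxia 10 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 0.00679, and adjusted p = 0.586 with an estimated correlation). Examples were PGK1 (-1.56 ± 0.12, adjusted p = 0.000167), PGAM1 (-1.36 ± 0.13, adjusted p = 0.000383) and PFKFB3 (-1.28 ± 0.12, adjusted p = 0.000358). Of their members 12, 13 and 19 lay at or above the median level of all genes, where 3272 of the 3370 lower calls were.

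Camera did not call the other programme lists with MEKi. Fry called dendritic cell maturation higher (adjusted p = 0.0117, 0.00422 to 0.699 over its alternatives) and ATF4 and endoplasmic reticulum stress lower (0.0315, 0.0315 to 0.671). Of 23 dendritic cell maturation genes 8 rose and 4 fell (11 and 5 adjusted over the list alone, camera adjusted p = 0.451). CXCR4 (2.79 ± 0.30, adjusted p = 0.000564) rose with CCR7, IDO1 and LAMP3, while the costimulatory CD86 (-1.96 ± 0.23, adjusted p = 0.000846) and the adhesion molecule ICAM1 (-1.98 ± 0.27, adjusted p = 0.00159) fell. Of 13 MHC class II genes 3 rose and 1 fell (2 and 1 adjusted over the list alone, 0.801), with CIITA, the master regulator of the class, at 1.65 ± 0.32 (adjusted p = 0.00698) and the protease gene CTSH at -1.46 ± 0.18 (adjusted p = 0.00111). The median of the MHC class II list was 0.12 as deposited, 0.35 after quantile normalization once more and -0.07 after centring. After quantile normalization the lists of dendritic cell maturation (adjusted p = 0.00839, 0.00422 to 0.699 over its alternatives) and MHC class II (0.0107, 0.00991 to 0.899) were called higher. Of 21 interferon-stimulated genes 2 rose and 1 fell (1 and 0 adjusted over the list alone, median -0.53, 0.123), with IRF7 at 1.08 ± 0.16 (adjusted p = 0.00247) and GBP1 at -1.65 ± 0.54 (adjusted p = 0.0456). Of 16 NF-kB targets REL rose (1.55 ± 0.17, adjusted p = 0.000677) and 4 fell, TNF among them (-1.61 ± 0.34, adjusted p = 0.0102, 2 rose and 6 fell adjusted over the list alone, 0.404). Of 22 chemokines and receptors 3 rose and 3 fell (2 and 3 adjusted over the list alone, 0.308), with CCR1 at -1.89 ± 0.24 (adjusted p = 0.00113) and CCR2 at 0.35 ± 0.07 (adjusted p = 0.00764). Of 17 ATF4 and endoplasmic reticulum stress genes 2 rose and 7 fell (2 and 7 adjusted over the list alone, 0.0973), among them PSAT1 of serine synthesis (-2.42 ± 0.27, adjusted p = 0.000656).

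Among 8 anti-apoptotic genes BCL2 rose and MCL1 fell with MEKi (1 and 1 adjusted over the list alone, camera adjusted p = 0.451). Of 14 pro-apoptotic genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, 0.852), with FAS at 0.62 ± 0.09 (adjusted p = 0.00172) and BID, a BH3-only gene, at -2.20 ± 0.19 (adjusted p = 0.000271). Of 8 heat shock genes 3 rose and 2 fell (3 and 2 adjusted over the list alone, 0.774), with HSPA1A at 1.70 ± 0.30 (adjusted p = 0.00489) and HSPH1 at -0.85 ± 0.14 (adjusted p = 0.00316). Of 7 aryl hydrocarbon receptor targets 1 rose and 2 fell (1 and 2 adjusted over the list alone, 0.665), among them NQO1 (-1.08 ± 0.21, adjusted p = 0.00753). Of 18 lysosome and autophagy genes 4 rose and 1 fell (3 and 1 adjusted over the list alone, 0.714), among them SQSTM1, a receptor of autophagy (0.58 ± 0.12, adjusted p = 0.01).

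Camera called no marker list of another cell type with MEKi. Fry called 6 of the 12 higher: plasmacytoid dendritic cell (adjusted p = 0.00255, 0.00255 to 0.699 over its alternatives), eosinophil (0.00527, 0.00527 to 0.802), neutrophil (0.0291, 0.0291 to 0.994), B and plasma cell (0.0315, 0.0315 to 0.699), erythroid (0.0315, 0.0315 to 0.97) and fibroblast markers (0.0414, 0.0414 to 0.817). Fry does not compare a list with other genes, and genes under the median level had a median change of 0.171. At or above that level lay 1 of 6 eosinophil, 0 of 8 neutrophil, 0 of 4 erythroid and 0 of 7 fibroblast markers. Of plasmacytoid dendritic cell markers 4 of 6 did, and of B and plasma cell markers 4 of 8. These calls cannot be told apart from a shift common to many genes. T cell markers rose in 3 of 13 genes (0 adjusted over the list alone; CD5, CD3E and CD8A by 0.19 to 0.47, camera adjusted p = 0.451). B and plasma cell markers rose in 3 of 8 (3 adjusted over the list alone, 0.298) and eosinophil markers in 3 of 6 (4 adjusted over the list alone, 0.244). After quantile normalization once more 0 genes of these 3 lists rose, and the sign of the T cell median turned. CSF1R, a receptor of macrophages and other myeloid cells, fell (-2.42 ± 0.40, adjusted p = 0.00387) among macrophage and monocyte markers (2 of 13 rose and 1 fell, 2 and 1 adjusted over the list alone, camera adjusted p = 0.903). Osteoclast markers rose in 1 of 7 and fell in 2 (1 and 2 adjusted over the list alone, 0.833). Plasmacytoid dendritic cell markers rose in 2 of 6 and fell in 1 (4 and 1 adjusted over the list alone, 0.451). Endothelial markers rose in 3 of 7 and fell in 2 (3 and 2 adjusted over the list alone, 0.932). Of 7 keratinocyte markers 1 rose (1 adjusted over the list alone, 0.498), as did 1 of 4 erythroid markers (1 adjusted over the list alone, 0.451). None passed of 7 NK cell (0.298), 8 neutrophil (0.451) and 7 fibroblast markers (0.704). The median, mean and test differed in sign for pro-apoptotic genes, heat shock, macrophage, osteoclast and endothelial markers.

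The share of higher calls with MEKi was 55.9% as deposited, 26.9% after quantile normalization once more (5156 genes passed), 15.4% after centring and 30.9% after cyclic loess, and 3790 to 5548 genes passed without 1 pair. CCR7 (adjusted p 0.000748 to 0.0185) and CD207 (0.000198 to 0.00558) passed under every alternative, while without the block the adjusted p was 0.118 for BCL2L11 (0.000493 to 0.118), 0.0511 for BCL2 (0.0221 to 0.123), 0.0948 for the immediate early list (5.77e-07 to 0.699) and 0.0772 for the Langerhans cell and LCH list (0.00902 to 0.586), and after quantile normalization once more the latter had 0.114 and the glycolysis list 0.289 (0.00255 to 0.586).

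**Figure D3:**
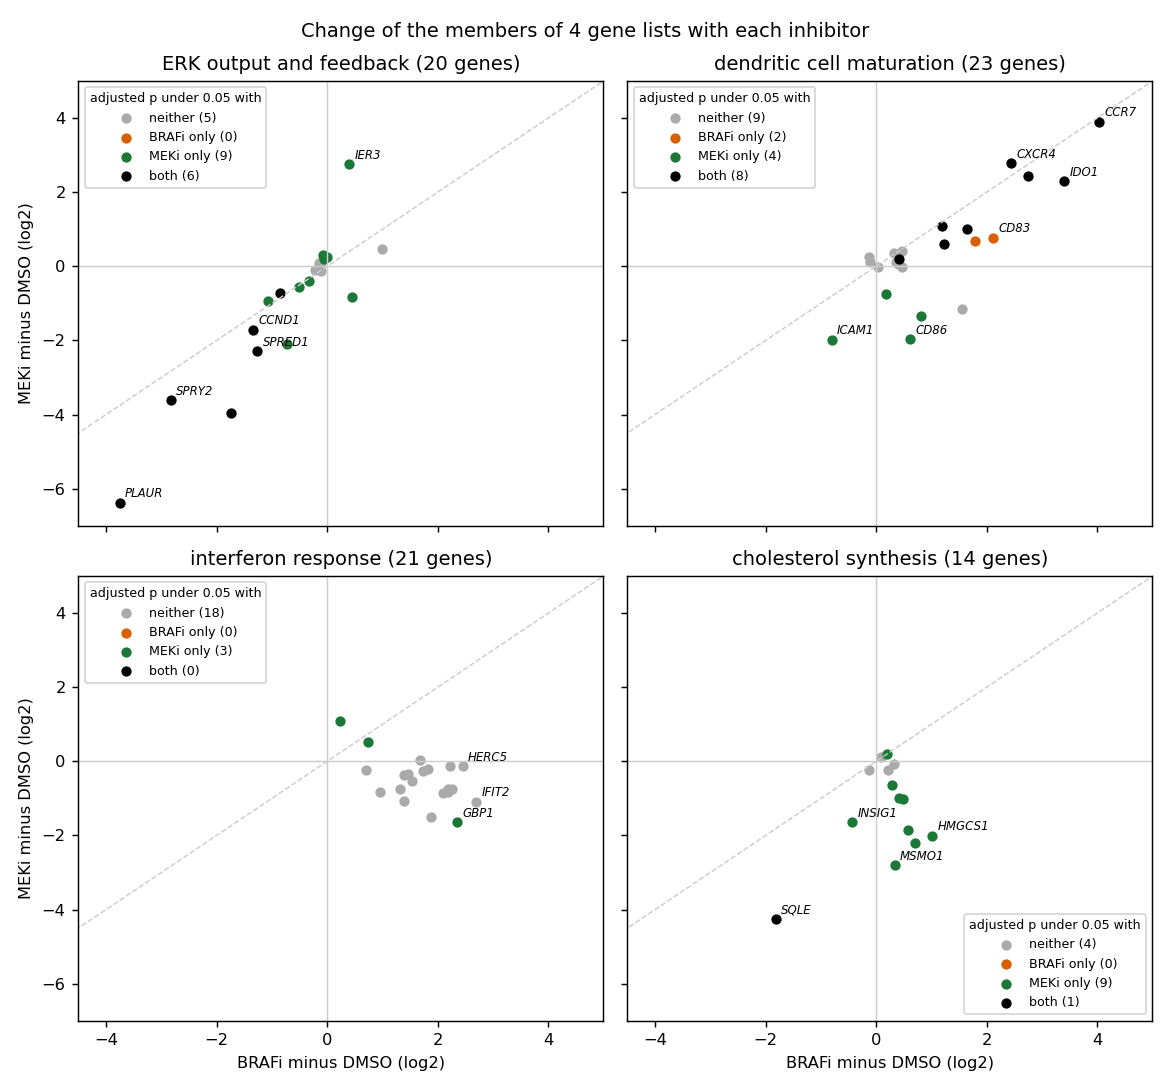
Change of the members of 4 gene lists with BRAFi (x axis) and MEKi (y axis) against DMSO, log2, coloured by the inhibitor with which they passed; the dashed line marks equal change. Of 20 ERK output genes 6 passed with both inhibitors and 9 with MEKi and not BRAFi, and of 14 cholesterol synthesis genes 1 passed with both and 9 with MEKi and not BRAFi.

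The mean of both inhibitors against DMSO asked what inhibitor treatment changed on average. A call for the mean can come mostly from 1 inhibitor, so it does not show a change common to both. CRLF2 (4.13 ± 0.24, adjusted p = 0.00024) and CCR7 (3.97 ± 0.46, adjusted p = 0.00218) had the largest rises. MIR221 (-5.56 ± 0.24, adjusted p = 0.000179), CLEC5A (-5.12 ± 0.41, adjusted p = 0.000717) and PLAUR (-5.07 ± 0.25, adjusted p = 0.000219) had the largest falls. Each had the same sign in 4 of 4 pairs. In all, 2358 genes passed, 754 higher and 1604 lower, and 501 changed 2-fold or more. Next among the rises came IDO1 (2.85 ± 0.30), CXCR4 (2.61 ± 0.26), LAMP3 (2.59 ± 0.38), NR4A3 (2.50 ± 0.35), P2RY10 (2.43 ± 0.34), ARAP2 (2.35 ± 0.14), DAPP1 (2.31 ± 0.28), SLC9A9 (2.25 ± 0.24), ZFP36 (2.18 ± 0.32) and ADAM28 (2.13 ± 0.16). Next among the falls came MMP12 (-4.23 ± 0.59), IL1B (-3.93 ± 0.62), SLAMF8 (-3.77 ± 0.24), MIR222 (-3.63 ± 0.88, adjusted p = 0.0363), CCL1 (-3.47 ± 0.51), EMP1 (-3.44 ± 0.33), NRP1 (-3.28 ± 0.28), SPRY2 (-3.22 ± 0.21) and RESF1 (-3.19 ± 0.26). Mean levels with DMSO, BRAFi and MEKi were 12.1, 12.8 and 15.8 for ZFP36 and 13.3, 11.9 and 7.81 for CCL1. Most of these 2 changes therefore came from MEKi. For CCR7 the levels were 10.1, 14.1 and 14.0.

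Called lists with higher genes included dendritic cell maturation, in which 10 of 23 members rose and ICAM1 fell (13 and 3 adjusted over the list alone, median 0.31, camera adjusted p = 0.000989, and adjusted p = 0.181 with an estimated correlation). Of 18 immediate early genes 4 rose (9 rose and 1 fell adjusted over the list alone, median 0.38, camera adjusted p = 0.00314, and adjusted p = 0.69 with an estimated correlation). Of 13 MHC class II genes 5 rose and CTSH fell (7 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 0.00248, and adjusted p = 0.456 with an estimated correlation), with HLA-DOA at 1.08 ± 0.16 (adjusted p = 0.0052). Of 21 interferon genes IRF1 and IRF7 rose (2 adjusted over the list alone, median 0.64, camera adjusted p = 0.0104, and adjusted p = 0.78 with an estimated correlation). The interferon list's median was 1.74 with BRAFi and -0.53 with MEKi, so its call for the mean is not a rise common to both inhibitors.

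Of 20 ERK output and feedback genes 10 fell and DUSP5, named after its values were seen, rose for the mean of both inhibitors (10 and 2 adjusted over the list alone, median -0.27, camera adjusted p = 5.46e-05, and adjusted p = 0.456 with an estimated correlation). DUSP6 fell by 2.84 ± 0.28 (adjusted p = 0.00112) and CCND1 by 1.52 ± 0.14 (adjusted p = 0.00103), each in 4 of 4 pairs. Senescence-associated secretory genes fell in 10 of 22 members (11 adjusted over the list alone, median -0.51, 0.000219, and adjusted p = 0.456 with an estimated correlation). Ribosome biogenesis genes fell in 5 of 12 (8 adjusted over the list alone, median -0.43, 4.45e-06, and adjusted p = 0.456 with an estimated correlation), with NOP16 at -1.25 ± 0.17 (adjusted p = 0.00361). Cholesterol synthesis genes fell in 3 of 14 (3 fell and 1 rose adjusted over the list alone, median -0.28, 0.00426, and adjusted p = 0.456 with an estimated correlation). Genes of glycolysis and hypoxia fell in 7 of 20 and rose in 1 (8 and 1 adjusted over the list alone, median -0.05, 0.0233, and adjusted p = 0.456 with an estimated correlation). Medians with BRAFi and with MEKi were -0.05 and -0.88 for ribosome biogenesis, 0.30 and -0.999 for cholesterol synthesis, and 0.07 and -0.30 for glycolysis. Camera called none of these lists lower with BRAFi. ATF4 and endoplasmic reticulum stress genes fell in 6 of 17 (7 fell and 1 rose adjusted over the list alone, median -0.12, 0.0104, and adjusted p = 0.456 with an estimated correlation). Cell cycle genes fell in 3 of 24 (3 adjusted over the list alone, median -0.09, camera adjusted p = 0.0256, and adjusted p = 0.465 with an estimated correlation).

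Of the 8 study genes CCR7 and BCL2L11 rose for the mean of both inhibitors (3 rose and 1 fell adjusted over the list alone, again no independent evidence), and camera did not call the list (adjusted p = 0.147). Fry called it higher (adjusted p = 0.0218), as did camera after quantile normalization once more (adjusted p = 0.03, 0.0173 to 0.465 over its alternatives), centring (0.0314) and cyclic loess (0.0173). Of 16 Langerhans cell and LCH markers CD207 (-2.85 ± 0.42, adjusted p = 0.00518) and CD52 (-0.88 ± 0.22, adjusted p = 0.0398) fell and ID2 rose (0.82 ± 0.21, adjusted p = 0.0447), without a call of the list (0.0615). T cell markers, with IL7R at 1.15 ± 0.26 (adjusted p = 0.0279), were not called (0.167). BCL2L11 rose by 1.28 ± 0.14 (adjusted p = 0.00159) and MAP2K1 fell by 0.75 ± 0.15 (adjusted p = 0.0204). CD207 and MAP2K1 passed with MEKi and did not pass with BRAFi. BCL2 (0.95 ± 0.29, adjusted p = 0.0813), MCL1 (-0.69 ± 0.23, adjusted p = 0.0982), CCL21 (0.15, 0.255) and BCL2A1 (0.03) did not pass. Camera adjusted p-values of the other lists lay between 0.431 for osteoclast markers and 0.986 for anti-apoptotic genes. Fry called 1 of these, plasmacytoid dendritic cell markers, higher (adjusted p = 0.0232, 0.0232 to 0.702 over its alternatives). The median, mean and test differed in sign for the kinases, chemokines, pro-apoptotic genes, NF-kB targets, heat shock, aryl hydrocarbon receptor targets, macrophage, osteoclast and endothelial markers. Without the pair block 1030 genes passed, without 1 pair 830 to 1485, and the MHC class II and interferon lists had adjusted p = 0.245 (4.2e-06 to 0.456 over its alternatives) and 0.514 (1.14e-05 to 0.78) without the block.

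MEKi against BRAFi tested the difference between the inhibitors itself. Interferon-stimulated genes were lower with MEKi than with BRAFi: 18 of 21 fell and IRF7 rose (19 and 1 adjusted over the list alone, median -2.07, camera adjusted p = 1.61e-08, and adjusted p = 0.382 with an estimated correlation). GBP1, a guanylate-binding protein, fell 16-fold (-4.00 ± 0.54, adjusted p = 0.00213), IFI44L by 3.01 ± 0.44 (adjusted p = 0.00291) and IFI6 by 2.46 ± 0.44 (adjusted p = 0.00553), each in 4 of 4 pairs. CD207 fell by 3.79 ± 0.48 (adjusted p = 0.00179). CCR7 (-0.13 ± 0.54, adjusted p = 0.855) and BCL2L11 (0.12 ± 0.16, adjusted p = 0.551) did not pass. In all, 8219 genes passed, 4927 higher (59.9%) and 3292 lower, and of genes under the median level 3916 rose and 45 fell. The split turned with the scaling: 992 were higher and 2625 lower after quantile normalization once more (27.4% higher), 752 and 5104 after centring (12.8%), and 959 and 2514 after cyclic loess (27.6%).

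The largest rises were of SNORD60 (3.02 ± 0.86, adjusted p = 0.028), RASD1 (2.95 ± 0.50), ZFP36 (2.94 ± 0.37), SCARNA7 (2.89 ± 0.48), MTRNR2L2 (2.87 ± 0.33) and RNU5A-1 (2.73 ± 0.41). The largest falls were of CLEC5A (-4.39 ± 0.47), TNFSF10 (-4.28 ± 0.81), CCL1 (-4.13 ± 0.59), CXCL10 (-4.05 ± 1.29, adjusted p = 0.0399), GBP1 and FPR3 (-3.92 ± 0.37, adjusted p = 0.000746). Each had the same sign in 4 of 4 pairs.

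Genes of dendritic cell maturation were lower with MEKi than with BRAFi in 11 of 23 members and higher in 1 (11 and 1 adjusted over the list alone, median -0.34, camera adjusted p = 0.000306, and adjusted p = 0.138 with an estimated correlation). The costimulatory genes CD86 (-2.58 ± 0.23, adjusted p = 0.000604), CD80 (-2.71 ± 0.44, adjusted p = 0.00397) and CD40 (-0.93 ± 0.10, adjusted p = 0.0012) were among them. MHC class II genes fell in 6 of 13 members (7 adjusted over the list alone, median -0.56, 0.000306, and adjusted p = 0.382 with an estimated correlation), with HLA-DPA1 at -0.87 ± 0.14 (adjusted p = 0.00396). NF-kB targets fell in 9 of 16 (9 adjusted over the list alone, median -0.50, 0.000681, and adjusted p = 0.382 with an estimated correlation), among them the survival gene BCL2A1 (-2.11 ± 0.35, adjusted p = 0.0045, 4 of 4 pairs) and CD83 (-1.35 ± 0.30, adjusted p = 0.0116). Cholesterol synthesis genes fell in 9 of 14 (9 adjusted over the list alone, median -1.29, 1.58e-07, and adjusted p = 0.294 with an estimated correlation), with MSMO1 at -3.14 ± 0.18 (adjusted p = 0.000263) and HMGCS1 at -3.02 ± 0.30 (adjusted p = 0.000908). Ribosome biogenesis genes fell in 10 of 12 (10 adjusted over the list alone, median -0.96, 2.29e-07, and adjusted p = 0.382 with an estimated correlation), with RRS1 at -2.35 ± 0.30 (adjusted p = 0.00189).

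Genes of glycolysis and hypoxia also fell, in 7 of 20 members (7 adjusted over the list alone, median -0.32, camera adjusted p = 0.00331, and adjusted p = 0.382 with an estimated correlation). Chemokines and receptors fell in 5 of 22 and CCR2 rose (5 and 1 adjusted over the list alone, median -0.28, 0.0273, and adjusted p = 0.382 with an estimated correlation). Langerhans cell and LCH markers fell in 4 of 16 and rose in 2 (7 and 2 adjusted over the list alone, median -0.39, 0.0341, and adjusted p = 0.382 with an estimated correlation). Senescence-associated secretory genes fell in 6 of 22 and rose in 1 (6 and 1 adjusted over the list alone, median -0.18, 0.0358, and adjusted p = 0.512 with an estimated correlation).

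Of the 8 study genes BCL2A1 fell and CCL21 rose (0.25 ± 0.09, adjusted p = 0.0492) between MEKi and BRAFi (1 fell and 0 rose adjusted over the list alone, no independent evidence, camera adjusted p = 0.541). The kinase genes ARAF (-0.45 ± 0.12, adjusted p = 0.0206) and MAP2K1 (-0.77 ± 0.18, adjusted p = 0.0141) fell, 2 of 4 (2 adjusted over the list alone, 0.353). ERK output genes went both ways, with 5 of 20 higher and 6 lower (5 and 6 adjusted over the list alone, 0.203), among them DUSP6 (-2.21 ± 0.32, adjusted p = 0.00279) and PLAUR (-2.62 ± 0.29, adjusted p = 0.00107). Immediate early genes rose in 9 of 18 and fell in 2 (11 and 2 adjusted over the list alone, 0.0985), with JUNB at 1.75 ± 0.35 (adjusted p = 0.00865) and EGR1 at 1.58 ± 0.32 (adjusted p = 0.00922). After quantile normalization once more the immediate early list was called higher (adjusted p = 4.93e-06, 2.62e-06 to 0.627 over its alternatives) and the cell cycle list lower (0.0362, 0.0344 to 0.562). The remaining lists had camera adjusted p-values from 0.0621 for the cell cycle to 0.86 for macrophage and monocyte markers. Fry called 9 of them. Anti-apoptotic genes were called lower (adjusted p = 0.0293, 0.0293 to 0.674 over its alternatives). The other 8, marker lists of other cell types, were called higher (0.0028 for eosinophil to 0.0302 for keratinocyte markers, with highest values over their alternatives of 0.412 to 0.892). Genes under the median level had a median difference of 0.204, so fry cannot tell these 8 calls apart from a shift common to many genes. The median, mean and test differed in sign for pro-apoptotic genes, ATF4 genes, heat shock, aryl hydrocarbon receptor targets, lysosome, T cell and macrophage markers.

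After quantile normalization once more 3617 genes passed for MEKi against BRAFi, and 7 of the 10 lists were no longer called: dendritic cell maturation (adjusted p = 0.144, range 3.21e-05 to 0.163), MHC class II (0.244, 5.95e-05 to 0.382), NF-kB targets (0.32, 7.34e-05 to 0.386), glycolysis (0.331, 0.00169 to 0.407), chemokines (0.18, 0.0171 to 0.562), Langerhans cell and LCH markers (0.144, 0.00486 to 0.382) and senescence-associated secretory genes (0.311, 0.00873 to 0.562). Without 1 pair 4023 to 4727 genes passed, 44.8% to 52.8% of them higher, CCL21 passed under few alternatives (0.0406 to 0.705), and CXCL10 had an adjusted p of 0.307 without the block (0.0319 to 0.307).

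**Figure D4:**
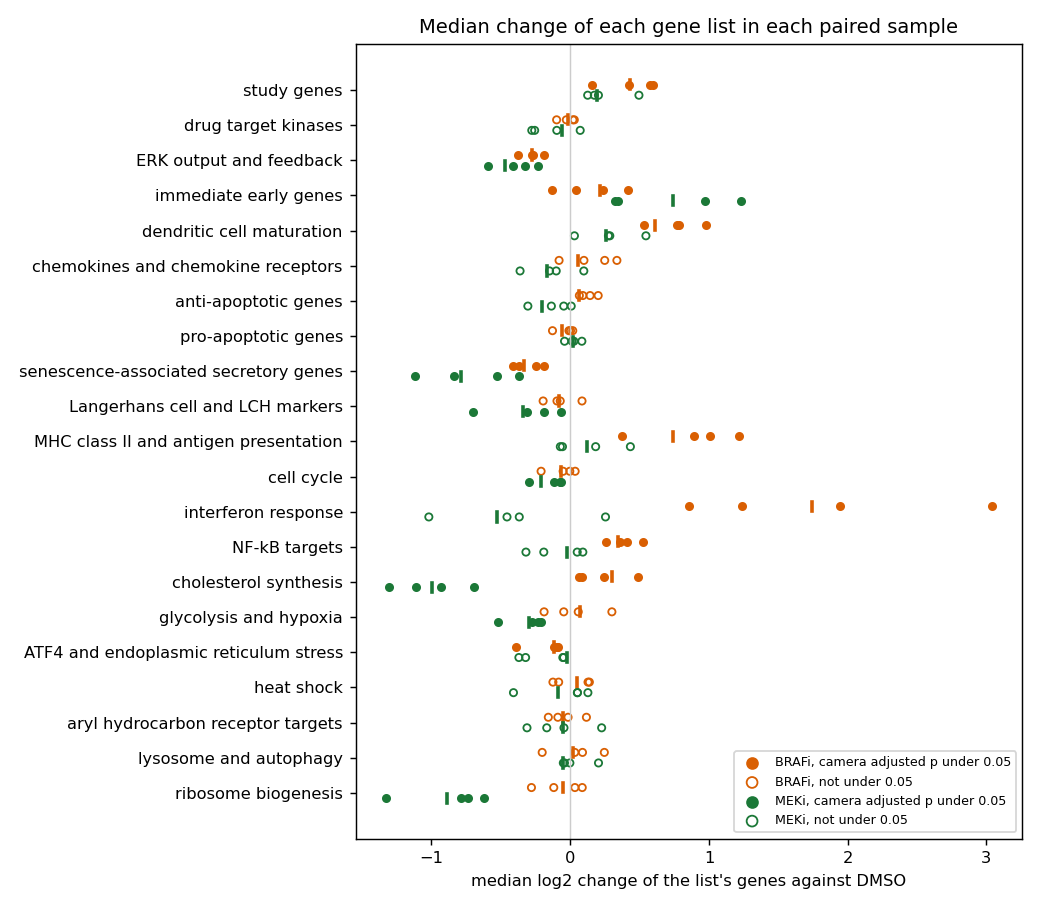
Median log2 change of each programme list against DMSO in each of the 4 paired samples (points; vertical bars, median over the pairs' mean changes; filled points, camera adjusted p under 0.05). The interferon list had a median of 1.74 with BRAFi and -0.53 with MEKi, and the cholesterol list 0.30 and -0.999, and these signs held under the other scalings.

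The responses to the 2 inhibitors were compared across genes, which are not independent replicates. Of the 207 genes higher with BRAFi 121 were also higher with MEKi, and of the 166 lower ones 164 were also lower, CLEC5A, PLAUR and SPRY2 among them. Independent lists of these sizes would share 39.6 and 25 genes, a figure that leaves the shared DMSO arrays out. Simulated unchanged groups against shared controls shared 0 and 0.02 genes, but had on average 0.13 and 0.04 calls per inhibitor, too few to show what shared controls add. Part of the excess may come from the shared DMSO arrays. Of the 373 genes 5 passed in opposite directions, and 202 differed between the inhibitors. Of the 373 genes 349 had the same sign with MEKi whatever the threshold. The log2 changes of all 22349 genes correlated at 0.443 (Pearson), against 0.501 ± 0.0128 (SD, 100 simulations) for unchanged groups. The same sign was found in 51.2%, against 66.7%. Shared controls alone set these 2 simulated values, so they do not show that the responses agree less than unchanged groups. The median change of all genes was also 0.102 with MEKi and -0.0228 with BRAFi, which bears on the share of same signs. The covariance of the log2 changes was 0.0744, against 0.0136 in the simulations, a difference of 0.0608. With separate DMSO arrays for each inhibitor the correlation was 0.163 to 0.523 and the covariance 0.0333 to 0.0991 over 6 splits.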

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

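The tests of array background, of centring and of CD1A were chosen only after the results they bear on had been seen, and so was cyclic loess. In 2 of the tests the bound set beforehand was missed by a small margin and the reading was kept, as said at each.

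Genes under the median level were higher and brighter genes lower on the MEKi arrays, which may in part come from a compressed signal range, a common shift or a higher background. After quantile normalization once more 290 of the 2912 dim genes that rose (9.96%) still passed and were higher, but after centring, which leaves the range as it is, only 354 (12.2%) did, so a compressed range and a common shift cannot be told apart for these rises. The lowest background of a MEKi array lay 0.15 above the highest of the other 8 arrays (3.558 and 3.408), in line with a higher background as a source of the dim rises. Of the 1142 genes that fell 2-fold or more, 902 (79.0%) were still 2-fold lower, 1 point under the bound of 80% set beforehand, while 1113 still passed and were lower and their median went from -1.34 to -1.26, which argues against compression as the whole cause of the large falls. The 92 ERCC control probe sets were 0.191 higher with MEKi than with DMSO, beside 0.189 for the median of all probe sets. What sets the MEKi arrays apart, the inhibitor or a step of their handling or normalization that the sources used here do not give, is open and untested.

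The interferon list had a median change of 1.74 with BRAFi and -0.53 with MEKi, although over all genes 0 of 21 members passed with BRAFi (18 rose adjusted over the list alone) and with MEKi IRF1 and IRF7 rose and GBP1 fell. Between the inhibitors 18 members were lower with MEKi. Compression of the MEKi arrays is unlikely to account for this difference, since the median difference between MEKi and BRAFi was -1.96 after cyclic loess. A single pair does not carry the BRAFi median either: without 1 pair the median BRAFi change was 1.31 to 2.09. An effect of the inhibitors themselves stays open and was not tested apart from these arrays, and the list's call was lost with an estimated correlation.

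CD207 was lower on the MEKi arrays by more than a compressed range is likely to give, while a change in the sorted cells stays open. Its change was -4.54 after cyclic loess. CD1A, another marker of lesion cells, changed by -1.24, against -4.74 for CD207. Its level went from 12.0 with DMSO to 11.8 with MEKi in pair 1, 12.7 to 12.4 in pair 2, 12.5 to 10.1 in pair 3 and 13.3 to 11.3 in pair 4. Cells without CD207 would lower CD1A alike only if they also lacked CD1A, which was not tested. CD1A therefore cannot exclude a change in the sorted cells. Of the 200 genes closest to CD207 in mean level 1 fell as far (MMP12, -5.93), where the bound set beforehand was 0, and their median change was -0.24 and their 5th percentile -1.74. An effect of MEKi on the gene is a hypothesis that stays open and untested, in cells sorted for CD207 protein.

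Other groupings of the arrays were fitted for each comparison. For BRAFi against DMSO 709 genes passed in a fit of these 2 groups, and the highest of the other splits gave 0 (1 of 8 splits as large). For MEKi against DMSO the numbers were 4068 and 0 (1 of 8), and for MEKi against BRAFi 3559 and 0 (1 of 8). With 8 splits a share under 0.05 cannot be reached. With both inhibitors as 1 group, 281 genes passed, in a fit that differs from the contrast of the mean (2358 genes). Of 81 ways to take 1 array of each pair as the control, 2 gave as many, the real one and 1 other. These ways are not alike, since the MEKi arrays stand apart, so they cannot exclude chance. The highest other way, with the 4 MEKi arrays as the control, gave 9772 genes, which points to a structure of the samples in which the MEKi arrays stand apart from the other 8.

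Of 166 groups of 4 values, 6 had a value far from the other 3, where chance alone gives about 1 in 20, or 8.3. Background controls of BRAFi replicate 1 stood at 3.408, against 3.228 to 3.256 on the other 3 BRAFi arrays. Labelling spike-ins stood at 5.597 on the same array, against 5.243 to 5.293. The snRNA genes had a median of 13.46 on MEKi replicate 4, against 10.78 to 11.22. The median change of the ATF4 and endoplasmic reticulum stress list with BRAFi was -0.3921 in pair 4, against -0.1162 to -0.0912. BCL2L1 changed by 0.617 with MEKi in pair 3, against -0.2925 to -0.2542, and BCL2L11 differed between MEKi and BRAFi by 0.5071 in pair 3, against -0.0412 to 0.0443.

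The cholesterol synthesis list differed between the inhibitors, with a median difference of -1.29 (camera adjusted p = 1.58e-07, and adjusted p = 0.294 with an estimated correlation). Its median was higher with BRAFi and lower with MEKi than with DMSO in 4 of 4 pairs each. Control probe sets are not used by the comparisons of genes. Background, hybridization and ERCC controls were higher on the MEKi than on the DMSO arrays, by 0.402, 0.971 and 0.191. The 1343 named by a number differed by -0.403.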

How the results depend on the processing

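Cyclic loess, the test of protein-coding genes only and exchanges of array measures within pairs were chosen after seeing the data, and the other alternatives before. Without the replicate block 54 genes passed for BRAFi against DMSO (373 with it) and 1030 for the mean of both inhibitors (2358). The block moved the counts for MEKi against DMSO and MEKi against BRAFi by less than 1.5 times. Of 615 values of named genes and lists 387 passed. Without the block 134 of the 387 no longer passed, 3 others newly passed and 478 kept their side and direction.

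Leaving out 1 pair gave 62 to 177 genes for BRAFi, with 82, 87, 177 and 62 without replicates 1, 2, 3 and 4. It gave 3790 to 5548 for MEKi, with 3790, 4634 and 4035 without replicates 2, 3 and 4. For the mean it gave 830 to 1485, with 1485, 830, 1457 and 1094 without replicates 1 to 4, and for MEKi against BRAFi 4023 to 4727, with 4713, 4727, 4674 and 4023. Fewer pairs lower the counts by construction. Each omission ended 98 to 125 of the 387 calls and turned none.

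Array quality weights gave 1146 genes for BRAFi and 3706 for the mean. The MEKi arrays had the lowest weights, 0.475 to 0.592, against 0.798 to 2.43 on the other arrays. A lower weight means a larger spread around the fit, and without weights all comparisons share that spread. The cause of the higher counts was not tested further. A fit of only the 2 compared groups gave 709 genes for BRAFi, without the MEKi arrays, 4068 for MEKi and 3559 for MEKi against BRAFi. Leaving out genes under the median level gave 4529 for MEKi and 3934 for MEKi against BRAFi, with fewer genes tested. Every probe set tested on its own gave 17110 and 18510, of 68635 tested. Cyclic loess gave 4760 and 3473, and quantile normalization once more 3617 for MEKi against BRAFi.

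Scaling moved the split of calls. For MEKi against DMSO 55.9% of calls were higher, against 26.9% after quantile normalization (1388 higher, 3768 lower), 15.4% after centring (945, 5208) and 30.9% after cyclic loess (1469, 3291), with the median of all genes shifted by -0.164, -0.189 and -0.155. For MEKi against BRAFi 59.9% became 27.4% (992, 2625), 12.8% (752, 5104) and 27.6% (959, 2514), with shifts of -0.166, -0.202 and -0.17. For the mean 32% became 16.7% after centring (454, 2263), and for BRAFi 55.5% became 42% after quantile normalization (147, 203). Called changes turned their sign, all near 0. For MEKi against DMSO CD8A became -0.024, -2.25e-05 and -0.014 (quantile, centring, loess) and KDR -0.0037 and -0.0097 (quantile, loess). For MEKi against BRAFi CD8A became -0.018 and -0.014 (quantile, loess). With quantile, centring and loess CD5 became -0.0019, -0.0078 and -0.0059, EPX -0.055, -0.0093 and -0.053, CSF3R -0.015, -0.016 and -0.014, COL6A3 -0.057, -0.0084 and -0.057, KDR -0.068, -0.019 and -0.075, and KRT15 -0.033, -0.0014 and -0.028. These scalings also ended 77, 65 and 84 of the 387 calls, beside those that turned. The cause was not tested beyond the common shift.

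With an estimated correlation camera called 1 list for BRAFi (12 at the preset one), 0 for MEKi (8), 0 for the mean (11) and 0 for MEKi against BRAFi (10). Fry, which does not compare a list with other genes, called 5, 17 and 17 for BRAFi, MEKi and MEKi against BRAFi. For MEKi against BRAFi 4 lists were called without dim genes, 5 after quantile normalization and 6 after cyclic loess, which also called heat shock genes (0.0391, 0.0391 to 0.982 over the alternatives). The correlation of both responses across genes, 0.443, became 0.523 without dim genes, 0.544 after quantile normalization, 0.543 after cyclic loess and 0.357 to 0.502 without 1 pair. The remaining settings (trend and robust, mean of all probe sets, protein-coding genes only) ended 9 and 3 of the 387 calls and 7 of the 371 that could be tested again and moved no count by 1.5 times. Signal over background limits dim genes. Their median change with MEKi was 0.171, beside a difference of 0.402 in the background controls. That difference belongs to other probe sets and sets no bound on the change of a single gene.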

Other observations

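The comparisons of RNA classes below were chosen only after the gene results had been seen. Among RNA classes with MEKi against DMSO, 9 of 24 snRNA genes and 54 of 241 snoRNA genes rose, while 0 and 4 fell. The share of snoRNA genes that rose was near that of all genes, 4274 of 22349. The median of the snoRNA genes on an array differed by 0.192 between MEKi and DMSO (exact permutation p = 0.343, adjusted p = 0.45). After quantile normalization once more, centring and cyclic loess, 9, 6 and 9 snRNA genes and 29, 19 and 30 snoRNA genes rose. Of 1914 long non-coding RNA genes 533 rose and 39 fell as deposited, and 151 and 84 after quantile normalization. Of protein-coding genes 2909 rose and 3213 fell as deposited, and 736 and 3481 after quantile normalization, with the median change turning from 0.07 to -0.09. With BRAFi 0 of the 24 snRNA genes passed (median 0.28), and between MEKi and BRAFi 5 rose and 0 fell.

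Within the ERK output list IER3, named after its values were seen, rose 6.72-fold with MEKi (2.75 ± 0.55, adjusted p = 0.00787), while DUSP6 fell 15.4-fold. The immediate early gene ZFP36 rose 12.6-fold with MEKi (3.66 ± 0.37, adjusted p = 0.000478) and MYC, also named after its values were seen, fell (-0.77 ± 0.16, adjusted p = 0.0104).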
